A study of Homo sapiens with 36 samples.

How the data were processed

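RNA was measured in Panc1 cells, a line grown from a human pancreatic carcinoma. The 36 libraries were made from polyA RNA of a control line, a line with HIF-1α knocked out (HIF1KO) and 2 separately derived clones with HIF-2α knocked out (HIF2KO_A and HIF2KO_B), all edited with CRISPR-Cas9 per the labels. Each line was kept for 48 h under 3 conditions: normoxia (20% oxygen) in regular medium, hypoxia (1% oxygen) in regular medium, or hypoxia in a tumour interstitial fluid medium (TIFM), a culture medium made to resemble the fluid inside tumours. This gave 12 groups of 3 libraries, and the group and replicate number of each library came from its title. The genotype field of the labels calls the edited lines knockdowns and the titles call them knockouts; the word of the titles is used here. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

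The deposited values were whole-number counts per gene and library, in 1 table of 21487 genes. Per the submitters' processing notes, reads were handled with HISAT2 and featureCounts against the genome build GRCh38; their versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. All 36 columns were matched to libraries by the library names in the labels, with 0 columns of other samples. Of the gene identifiers, 21383 were paired with a symbol through a table of gene names, 96 through the GENCODE 29 annotation, and 8 had none. GENCODE 29 held 21409 of the identifiers and supplied gene lengths and positions. Without a stated strand setting, reads of a gene and an overlapping or antisense partner cannot be told apart, and members of near-identical families (such as MAGEA6, MT1X and APOL1) are uncertain. The total count per library ran from 16847193 to 42880035.

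Genes with too few counts were left out with the default rule of edgeR's filterByExpr over the 12 groups (a count of about 10 in a library of median size), which left 13864 genes. Libraries were scaled with TMM factors, and levels are given as CPM, the count scaled to the size of the library with those factors. Differences were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) in 1 fit of all 36 libraries with a mean for each group and 24 residual degrees of freedom; the common biological coefficient of variation was 0.149. Each p-value was adjusted over the genes tested with the Benjamini-Hochberg method within a comparison, and a gene was called changed at an adjusted p under 0.05. The standard error (SE) of a log2 change was its size divided by the square root of the test's F value. In the report a fitted change is not quoted for a gene with a mean under 0.5 CPM in a group compared; the levels are given. All group means rest on n = 3 libraries. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

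There were 22 comparisons: hypoxia against normoxia in each line, TIFM against regular medium in control cells, each knockout line against control in each condition, the difference between each knockout line and control in the response to hypoxia and in the response to TIFM, HIF1KO against the mean of the HIF2KO clones in hypoxia, and clone A against clone B in hypoxia. After the data had been seen, 4 comparisons were added: control cells in hypoxia with TIFM against normoxia, and TIFM against regular medium in each knockout line. The groups, comparisons, tests, gene lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined.

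A total of 21 gene lists was tested in each comparison with camera (limma), which sets the genes of a list against all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation; its p-values were adjusted over the lists of a comparison. The lists were glycolysis, hypoxia-inducible genes, genes described as HIF-2 targets, oxidative phosphorylation, the TCA cycle, cholesterol synthesis, fatty acid synthesis, the amino acid response, the unfolded protein response, proliferation, epithelial markers, mesenchymal markers, collagen and matrix, the interferon response, NF-kB and inflammation, NRF2 targets, iron handling, and markers of immune, endothelial, acinar and endocrine, and ductal cells. Some genes stand in more than 1 list.

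The genes named in the text were chosen by a rule. In the main comparisons these were the 8 largest rises and the 8 largest falls among named genes past the threshold with a mean of at least 5 CPM and, between 2 groups, all 3 libraries of one group above all 3 of the other. For HIF2KO a gene had to pass in both clones with the same sign, ranked by the smaller change. From each called list up to 4 members with the smallest adjusted p could be named, and up to 2 from other lists. In the other comparisons the 3 largest rises and 3 largest falls could be named. HIF1A, EPAS1, HIF3A, ARNT, ARNT2, VHL and EGLN2 were always examined.

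The alternatives were RLE scaling factors, DESeq2 (independent filtering off), no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were a fit without 2 libraries with few counts from long genes (control normoxia 3 and HIF1KO normoxia 2) and a fit with a length index as a covariate, the median log2 CPM (with 1 added) of the 20% of genes with the longest gene models (8235 bp or more) minus that of the 20% with the shortest (2785 bp or less). Overlaps between comparisons against the same control libraries were set beside 20 simulations of unchanged groups against those controls, and beside the overlap of independent lists. Other splits of the libraries were drawn up to 100 times per comparison.

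The tests were tested on simulated data drawn from the real means and library sizes, with 200 genes changed by known amounts. For hypoxia against normoxia in control cells (13756 genes), edgeR recovered 32.8, 71.6 and 90.9% of genes changed 1.5-, 2- and 4-fold. It called 6 of 13343 unchanged genes. For the difference between HIF1KO and control in the response to hypoxia (13756 genes) the shares were 17.9%, 52.2% and 89.4%, with 14 unchanged genes called. Camera called the 1 shifted list and 0 of 20 others.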

Results

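Gene expression was profiled by sequencing polyA RNA from Panc1 pancreatic carcinoma cells, to ask how HIF-1α and HIF-2α, the oxygen-regulated subunits of the hypoxia-inducible transcription factors, shape the response to low oxygen in a regular medium and in a tumour interstitial fluid medium (TIFM). A control line, an HIF-1α knockout line (HIF1KO) and 2 HIF-2α knockout clones (HIF2KO_A and HIF2KO_B) were each kept for 48 h in normoxia with regular medium, hypoxia with regular medium or hypoxia with TIFM. Every group held 3 libraries, 36 in all, and 13864 genes had enough counts to test. Levels below are mean CPM over n = 3 libraries, changes are log2 changes ± SE, and adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for gene lists. A list's call that is given without a second p-value also held with an estimated correlation between genes.

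The edited genes were examined first. HIF1A (ENSG00000100644; chromosome 14, 61695513 to 61748259, GRCh38) was lower in HIF1KO than in control in normoxia (30.3 against 102 CPM; -1.76 ± 0.16, adjusted p = 3.39e-10), hypoxia (51.7 against 77.2 CPM; -0.58 ± 0.15, adjusted p = 0.00306) and TIFM (34.8 against 113 CPM; -1.70, adjusted p = 3.88e-10). EPAS1, which encodes HIF-2α (ENSG00000116016; chromosome 2, 46293667 to 46386703), was lower in clone A in normoxia (34.3 against 128 CPM; -1.90, adjusted p = 2.91e-10), hypoxia (55 against 195 CPM; -1.83, adjusted p = 5.43e-10) and TIFM (38.1 against 229 CPM; -2.59, adjusted p = 5.14e-13). In clone B the EPAS1 fall was smaller, to 86.2 CPM in normoxia (-0.57, adjusted p = 0.00829), 102 CPM in hypoxia (-0.93, adjusted p = 5.66e-05) and 112 CPM in TIFM (-1.03, adjusted p = 1.32e-05). An edited gene can keep its mRNA, and these counts do not show protein. HIF1A was higher in clone B than in control in normoxia, hypoxia and TIFM, by 0.99, 0.65 and 0.74, and in clone A lower in normoxia (-0.50, adjusted p = 0.00858) and TIFM (-0.42, adjusted p = 0.0193) and unchanged in hypoxia (0.07, adjusted p = 0.748). Among partners and regulators, ARNT2, a dimer partner of the HIF-α subunits, was at 0.401 CPM in clone B against 6.87 CPM in control cells in hypoxia (adjusted p = 5.05e-14). VHL, which marks HIF-α for degradation, was 0.56 higher in HIF1KO in hypoxia (adjusted p = 0.00119). HIF3A stayed at or below 0.0528 CPM in every group, and EGLN2, a HIF prolyl hydroxylase, was listed at 0 counts in all 36 libraries, which may come from the annotation or the counting.

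**Figure D1:**
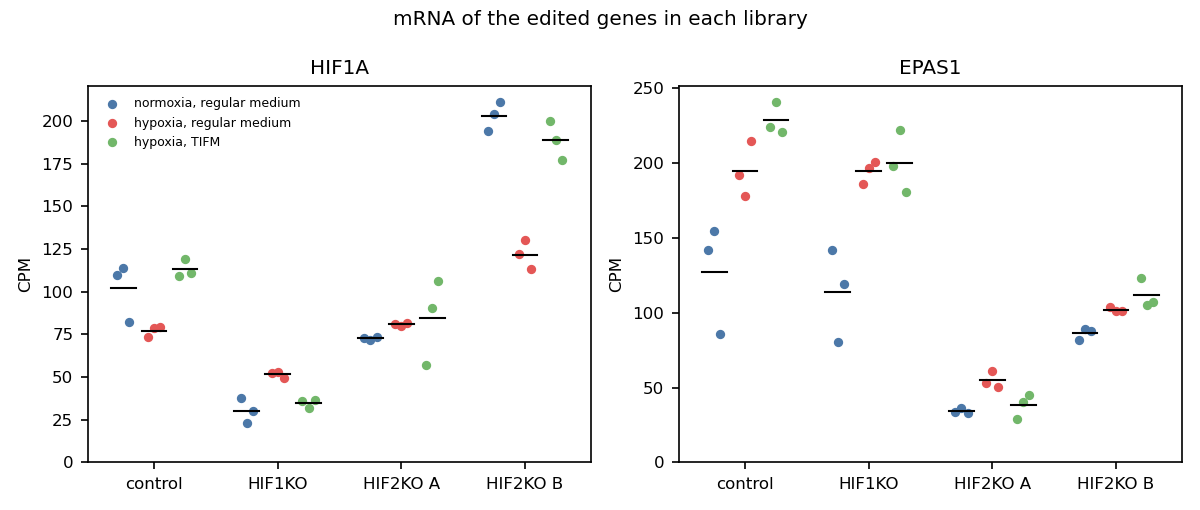
HIF1A and EPAS1 in CPM (vertical axis, starting at 0) for each of the 36 libraries, by line and condition, with a bar at each group mean. HIF1A lay lowest in HIF1KO (30.3 to 51.7 CPM by condition) and EPAS1 lowest in HIF2KO_A (34.3 to 55 CPM), with HIF2KO_B between clone A and control.

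In control cells, 48 h of hypoxia raised genes of glucose use and other known oxygen-regulated genes. IGFBP3, which binds insulin-like growth factors, rose from 0.826 to 15.8 CPM (4.24 ± 0.35), and PFKFB4, a regulator of glycolytic flux, from 11.8 to 169 CPM (3.83 ± 0.19). PDK1, a mitochondrial kinase that inhibits pyruvate dehydrogenase, rose from 11.5 to 107 CPM (3.21 ± 0.18), and NDRG1, a stress-responsive gene, from 5.21 to 57.7 CPM (3.46 ± 0.16). Further large rises were those of PPFIA4 (4.11), UPK1A (3.92) and the glycogen-targeting phosphatase subunits PPP1R3G (4.04) and PPP1R3C (3.18). Falls were smaller: the homeobox gene NKX6-2 (-1.97), the secretory-pathway gene AGR2 (from 154 to 52.4 CPM, -1.56), RFLNA (-1.45), PPP1R1B (-1.45), TENT5B (-1.35), SEMA6B (-1.32), EXOSC4 (-1.32) and SCARA3 (-1.30). In all, 3025 genes changed, 1508 higher and 1517 lower, and of the 546 that changed at least 2-fold 456 were higher and 90 lower. The length index gave 4592. A fit of these 6 libraries alone called 438 genes, of which 374 (85.4%) were higher and 64 lower. Leaving out control hypoxia 3 gave 1892 genes and leaving out control normoxia 3, whose composition stood apart, gave 1915. EXOSC4 was at -0.57 (adjusted p = 0.117) without that library and HIF1KO normoxia 2.

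Known hypoxia targets moved almost as a block in control cells. Of 28 hypoxia-inducible genes 27 rose and 0 fell (27 and 0 adjusted over the list alone, median 1.99, adjusted p = 1.83e-114), among them STC2 (2.29), INSIG2 (2.60) and AK4 (2.46). Glycolysis followed, with 18 of 20 genes higher and 0 lower (18 and 0 adjusted over the list alone, median 1.20, adjusted p = 3.77e-40). HK2, the first enzyme of the pathway, went from 7.55 to 68.9 CPM and PGK1 from 785 to 2690 CPM. Of 17 genes described as HIF-2 targets, 12 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.26, adjusted p = 1.62e-16), including the lipid-droplet gene PLIN2 (28.5 to 80.4 CPM) and CITED2 (1.60). The amino acid response, genes driven by ATF4 when amino acids run short, rose in 17 of 27 members with 0 falls (19 and 0 adjusted over the list alone, median 0.63, adjusted p = 1.62e-16), for instance ATF3 (1.98), VLDLR (2.17) and SESN2 (0.99). Cholesterol synthesis rose in 11 of 22 genes with 0 falls (11 and 1 adjusted over the list alone, median 0.48, adjusted p = 8.61e-06; HMGCS1, 0.85). Fatty acid synthesis rose in 6 of 14 with 0 falls (7 and 0 adjusted over the list alone, median 0.35, adjusted p = 6.1e-06; ACSS2, 1.62, and the desaturase SCD, 1.33). Of 16 NF-kB and inflammation genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.77, adjusted p = 3.34e-04). Of 13 iron-handling genes 6 rose and 0 fell (7 and 2 adjusted over the list alone, median 0.24, adjusted p = 3.16e-04; STEAP3, 1.61).

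Proliferation genes moved the other way in control hypoxia: 14 of 27 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.35, adjusted p = 8.61e-06), with the mitotic genes CDC20 at -0.93, CCNB1 at -0.75 and AURKA at -0.54. Respiratory-chain genes were lower by the preset test only, 7 of 35 lower and 0 higher (12 and 0 adjusted over the list alone, median -0.45, adjusted p = 7.28e-05, or 0.522 with an estimated correlation). The unfolded protein response had 4 of 18 genes higher and 1 lower (5 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.0178, or 0.313 with an estimated correlation). Collagen and matrix had 4 of 22 higher and 0 lower (4 and 0 adjusted over the list alone, median 0.41, adjusted p = 0.0109, or 0.473 with an estimated correlation). Without control normoxia 3 and HIF1KO normoxia 2 the respiratory-chain and collagen calls were also lost (adjusted p = 0.358 and 0.225). Lists not called were the TCA cycle (1 higher and 3 lower of 16, median -0.19, adjusted p = 0.0618) and epithelial markers (3 and 4 of 17, -0.14, 0.752). Nor were mesenchymal markers (2 and 2 of 14, -0.26, 0.405), the interferon response (2 and 3 of 21, -0.18, 0.554) or NRF2 targets (3 and 4 of 14, -0.26, 0.587). Markers of other cell types were not called either, with immune markers (0 and 0 of 6, median -0.13, adjusted p = 0.845) among them. They also included endothelial (1 and 0 of 4, -0.11, 0.821, with a mean of 0.49 and thus of the other sign), acinar and endocrine (0 and 0 of 3, -0.07, 0.624) and ductal (1 and 1 of 6, 0.37, 0.587). Adjusted over each of these lists alone the counts were 1 and 5, 3 and 5, 2 and 3, 2 and 5, 3 and 4, 0 and 0, 1 and 0, 0 and 0, and 2 and 1, in the same order.

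HIF1KO cells still raised most hypoxia-inducible genes at 1% oxygen, but their glycolysis genes rose less. NOTCH3, a Notch receptor, went from 2.94 to 82 CPM (4.80 ± 0.28), NDRG1 from 8.7 to 131 CPM (3.91) and IGFBP3 from 5.1 to 71.2 CPM (3.80), while NES (-2.39), AGR2 (-2.32) and SULT2B1 (-2.02) fell. The list of hypoxia-inducible genes had 25 of 28 higher and 1 lower (25 and 2 adjusted over the list alone, median 1.78, adjusted p = 1.09e-48). That of HIF-2 targets had 13 of 17 higher and 1 lower (14 and 1 adjusted over the list alone, median 1.09, adjusted p = 1.23e-15). Glycolysis had 12 of 20 higher and 2 lower (13 and 2 adjusted over the list alone, median 0.46, adjusted p = 6.21e-07, or 0.117 with an estimated correlation). With hypoxia the amino acid response rose in 24 of 27 genes with 0 falls (25 and 0 adjusted over the list alone, median 1.10, adjusted p = 5.96e-27). In turn 17 of 27 proliferation genes fell while 2 rose (17 and 2 adjusted over the list alone, median -0.54, adjusted p = 3.02e-08). Cholesterol synthesis (16 of 22 higher, 1 lower, the same adjusted over the list alone, median 0.72, adjusted p = 1.02e-08), fatty acid synthesis (11 of 14 higher, 0 lower, 12 and 0 adjusted over the list alone, median 0.57, adjusted p = 1.96e-08) and iron handling (8 of 13 higher, 1 lower, 8 and 2 adjusted over the list alone, median 0.61, adjusted p = 2.56e-05) were higher. Calls of oxidative phosphorylation, the TCA cycle, the unfolded protein response and collagen did not hold with an estimated correlation. Altogether 5259 genes changed, 2656 higher and 2603 lower, and 3264 were called from these 6 libraries alone.

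The difference between HIF1KO and control in the response to hypoxia was tested directly. BNIP3, which promotes removal of mitochondria, rose from 118 to 596 CPM in control cells and stood at 72.2 and 56.5 CPM in HIF1KO (difference -2.69 ± 0.22, adjusted p = 1.19e-08). FAM162A, another HIF target, rose from 49.7 to 183 CPM in control cells against 30.4 and 29.2 CPM in HIF1KO (-1.94 ± 0.22). PGK1 rose by 1.78 in control cells and by 0.40 in HIF1KO (-1.38 ± 0.18), PFKFB4 by 3.83 and 2.24 (-1.59 ± 0.25), and PGM1 stood at 99.2 and 167 CPM in control against 90.5 and 88.2 CPM (-0.79 ± 0.11). PGAM1 and DOK3 moved in opposite directions, up by 0.87 and 1.18 in control cells, with HIF1KO at -0.29 and -0.47. PPFIA4 (-2.40), UPK1A (-2.12) and TSPEAR (-1.71) also responded less, and NES (-1.67) fell more. NOTCH3 (2.51), NPTX1 (1.64), CREB3L1 (1.63), SLFN5 (1.42), NIBAN1 (1.25), XKR7 (1.24) and STEAP2 (1.19) had a higher response.

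By list, the HIF1KO response to hypoxia was lower than that of control for glycolysis, with 6 of 20 genes lower and 0 higher (13 and 0 adjusted over the list alone, median -0.61, adjusted p = 3.65e-24). The same held for hypoxia-inducible genes, 7 of 28 lower and 1 higher (8 and 2 adjusted over the list alone, median -0.24, adjusted p = 1.22e-07). It was higher for the amino acid response, 6 of 27 higher and 0 lower (10 and 0 adjusted over the list alone, median 0.44, adjusted p = 2.25e-13; SESN2, 0.77, and ATF3, 0.86). Cholesterol synthesis had 1 of 22 higher and 0 lower (4 and 0 adjusted over the list alone, median 0.25, adjusted p = 2.87e-04; HMGCS1, 0.61). Fatty acid synthesis had 2 of 14 higher and 0 lower (3 and 0 adjusted over the list alone, median 0.29, adjusted p = 0.00222; ACSS2 and FASN). Proliferation was called lower with 0 of 27 members past the threshold in either direction, also adjusted over the list alone (median -0.21, adjusted p = 0.00222). HIF-2 targets were not called, though ARG2 (2.16) and TGFA (1.36) rose more in HIF1KO. In all 199 genes differed (108 higher, 91 lower); without HIF1KO hypoxia 1 the number was 126, without control normoxia 3 it was 398, and the libraries of these groups alone gave 43. DESeq2 gave 379 and the length index 836.

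**Figure D2:**
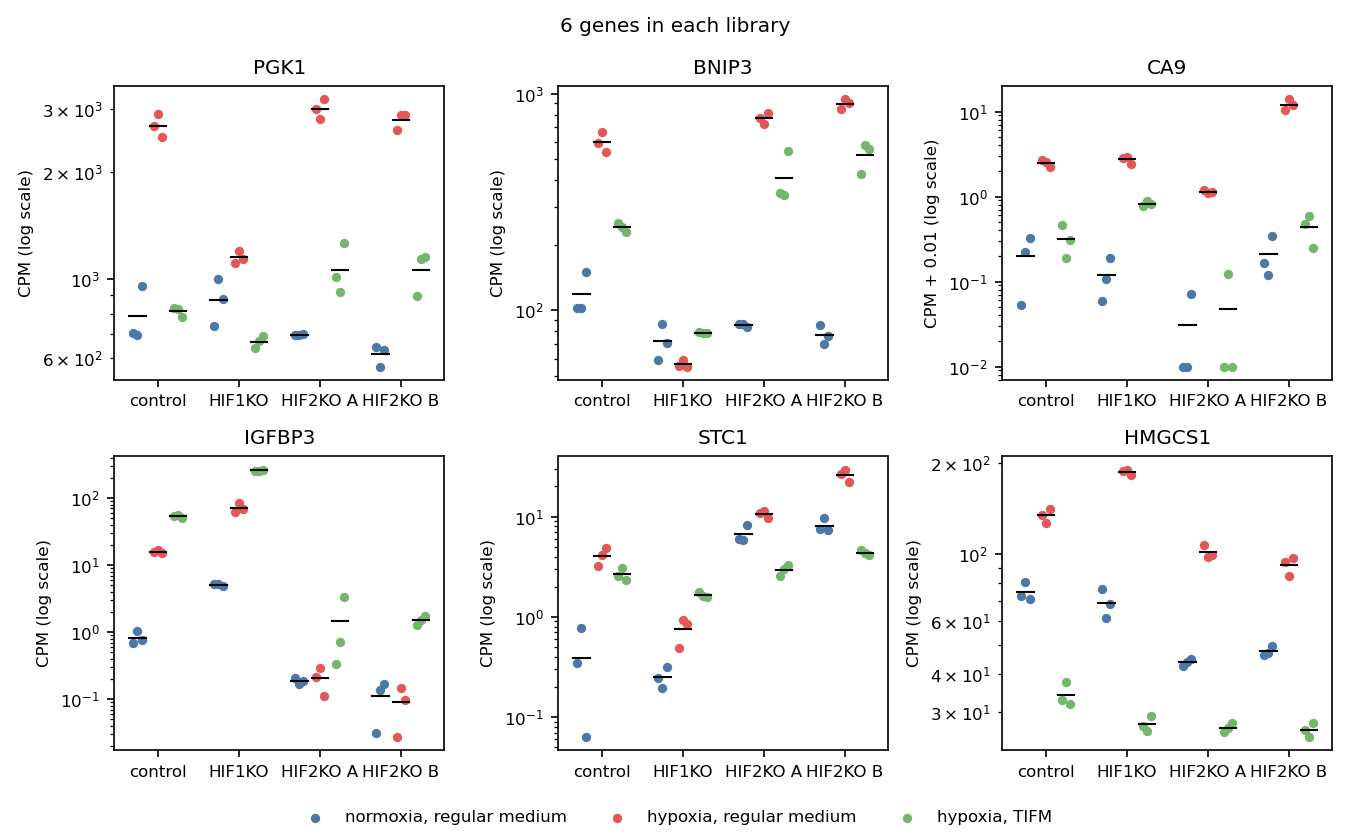
CPM on a log scale (CA9 with 0.01 added) of PGK1, BNIP3, CA9, IGFBP3, STC1 and HMGCS1 in each library, by line (horizontal axis) and condition (colour), with a bar at the group mean. PGK1 stood at 2690 CPM in control hypoxia and 1150 CPM in HIF1KO hypoxia, BNIP3 at 596 and 56.5 CPM, and HMGCS1 was lowest in TIFM in each of the 4 lines.

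Both HIF2KO clones kept a strong glycolytic response to hypoxia. PGK1 rose by 2.11 ± 0.13 in clone A and 2.19 ± 0.13 in clone B, and AK4, a mitochondrial adenylate kinase, from 0.456 to 45.1 CPM in A and from 1.46 to 95.4 CPM in B (6.04). TSPEAR rose from 20 to 321 CPM in A and from 9.08 to 272 CPM in B, PPFIA4 by 4.88 in A, and CA9, a carbonic anhydrase on the cell surface, from 0.2 to 12 CPM in B, while NKX6-2 fell by 1.57 and 1.54. Further genes named by the rule were TNS4 (26.3 to 8.28 CPM) and NES (-1.20), lower in A, and SAMHD1 (-1.08), lower in B. Glycolysis genes rose in 19 of 20 in A (19 and 0 adjusted over the list alone, median 1.38, adjusted p = 3.79e-52) and 20 of 20 in B (20 and 0 adjusted over the list alone, median 1.58, adjusted p = 1.06e-61), with 0 lower. Hypoxia-inducible genes rose in 26 and 27 of 28 with 0 falls (26 and 27 adjusted over the list alone, medians 1.70 and 1.95, adjusted p = 1.47e-94 and 1.29e-131). HIF-2 targets rose in 6 of 17 in each clone with 0 falls (6 and 0 adjusted over the list alone in each, medians 0.44 and 0.23, adjusted p = 4.44e-04 and 0.00102). Cholesterol and fatty acid synthesis, the amino acid response and NF-kB genes were also called higher in both clones, and proliferation lower. In clone A 2506 genes changed (1487 higher, 1019 lower) and in clone B 2128 (1325 higher, 803 lower). Dropping any 1 of the 6 libraries of clone A (hypoxia or normoxia 1, 2 or 3) gave 1463 to 1670 genes, and the 6 libraries alone gave 6941 in A and 4743 in B. Without control normoxia 3 and HIF1KO normoxia 2 the numbers were 4656 and 3342, and the length index gave 4596 in B.

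Genes described as HIF-2 targets responded less to hypoxia in both clones than in control cells. The list had 4 of 17 lower and 0 higher in A (7 and 0 adjusted over the list alone, median -0.46, adjusted p = 1.65e-11). In B it had 2 lower and 0 higher (8 and 0 adjusted over the list alone, median -0.55, adjusted p = 1.75e-11). There its median lay 0.58 above control in normoxia, 0.02 in hypoxia. IGFBP3 stood at 0.188 and 0.205 CPM in A and at 0.112 and 0.0904 CPM in B (adjusted p of the difference 0.0156 and 0.0404), and CITED2 responded less in A (-1.08, adjusted p = 0.00476). The inhibitor of differentiation ID2 responded less in both (-1.70 and -1.35). For the secreted hormone STC1 and for TRIM9 (-1.66 and -1.52) the smaller response went with a higher level in normoxia. STC1 rose from 0.393 to 4.07 CPM in control, from 6.7 to 10.7 CPM in A and from 8.14 to 26 CPM in B, and TRIM9 stood at 0.82 CPM in control normoxia against 7.29 and 6.17 CPM. Lower responses were also those of ANGPTL4 (-2.05), PGF (-1.74), FOXL1 (-1.96) and ITPR1 (-1.80) in A. In B these were ARRDC3 (-1.52), SERPINB9 (-1.68), WT1 (-1.56), GNG4 (-1.54) and ELFN2 (-1.44). Differences were positive in both for AK4 (3.58 in B), PDK3 (1.95 and 1.49), TSPEAR (1.20 and 2.10) and RFLNA (1.04 and 1.58). Further ones in A were GARIN2 (1.53), STARD4 (1.28) and, falling in control and rising in A, EREG (1.38) and SLC4A11 (1.17). In B they were RAB20 (0.311 to 3.66 CPM, 6.97 to 9.52 CPM in control), CLDN3 (1.44), BNIP3 (1.20), PPP1R1B (1.57) and AGR2 (1.52). RFLNA, PPP1R1B and AGR2 fell in control.

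Other lists in the HIF2KO responses to hypoxia were those of lipid synthesis. Cholesterol synthesis responded more in A, with 1 of 22 higher and 0 lower (1 and 0 adjusted over the list alone, median 0.22, adjusted p = 5.63e-04). In B it did so with 0 of 22 past the threshold, also adjusted over the list alone (median 0.25, adjusted p = 7.04e-04). Fatty acid synthesis had FADS2 and FASN, 2 of 14, higher and 0 lower in A (5 and 0 adjusted over the list alone, median 0.33, adjusted p = 4.31e-06) and in B (2 and 0 adjusted over the list alone, median 0.09, adjusted p = 0.0305, or 0.112 with an estimated correlation). Lower in A was the amino acid response, TRIB3 and SESN2 being 2 of 27 lower with 0 higher (3 and 0 adjusted over the list alone, median -0.30, adjusted p = 1.48e-09). In B epithelial markers were higher, 1 of 17 with 0 lower (5 and 0 adjusted over the list alone, median 0.44, adjusted p = 1.24e-05). Hypoxia-inducible genes in A lost their call with an estimated correlation (3 of 28 lower, 1 higher, 10 and 2 adjusted over the list alone, median -0.19, adjusted p = 0.0224, or 0.506 with an estimated correlation and 0.203 without control normoxia 3 and HIF1KO normoxia 2). In B glycolysis lost its call likewise (0 of 20 past the threshold, also over the list alone, median 0.38, adjusted p = 1.73e-04, or 0.276). So did the unfolded protein response (0 of 18, 2 higher over the list alone, median 0.15, adjusted p = 0.0144, or 0.276). The last was iron handling (1 of 13 lower, 0 higher, 1 and 0 adjusted over the list alone, median -0.05, adjusted p = 0.0341, or 0.112 with an estimated correlation and 0.096 without these libraries). In A 132 genes differed from control (43 higher, 89 lower) and in B 118 (60 and 58); without HIF2KO_B hypoxia 1 or control hypoxia 3 the number for B was 78. DESeq2 gave 237 and 223, the length index 543 and 434, the fit without control normoxia 3 and HIF1KO normoxia 2 gave 472 in A, and the libraries of these groups alone gave 67 in B. Both clones shared 60 of these genes (23 higher, 37 lower), where independent lists would share 0.186 and 0.372; they shared 99 with DESeq2, 100 without control normoxia 3 and HIF1KO normoxia 2 and 193 with the length index. The covariance of the differences was 0.15 against 0.11 in 20 simulations of lines that respond like control, and their correlation 0.50 against 0.51. These simulated lines shared 0 called genes. The 3 control libraries per condition could not be split, so part of the excess may still come from them.

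Of the 3025 genes that changed in control hypoxia, 2461 (81.4%) changed the same way in HIF1KO, 1467 (48.5%) in HIF2KO_A and 1299 (42.9%) in HIF2KO_B; with the length index 3557, 2277 and 2851 of 4592 did. Simulated lines that respond like control shared on average 2461, 2487 and 2547 of 3893 such genes. The change lay nearer to 0 than in control for 41.9, 78.4 and 78.8% of the 3025 genes, against 68.3, 68.5 and 68.5% in the simulations, because the genes were chosen by their change in control. By the test of the difference itself, the response lay nearer to 0 than in control for 63 genes in HIF1KO, 107 in A and 82 in B, and farther from 0 for 56, 7 and 19. These simulated lines gave means of 0.05, 0.05 and 0 genes nearer to 0. DESeq2 gave 120, 181 and 140 and the length index 244, 416 and 254. Without HIF1KO hypoxia 1, control hypoxia 2 or control normoxia 3 the 63 became 39, 40 or 99, and without control hypoxia 3 or control normoxia 3 the 2461 became 1543 or 1472. Control normoxia 3 and HIF1KO normoxia 2 shared a deviation from their groups (r = 0.93 across 10209 genes), and without both 1793 of 2392 control genes changed the same way in HIF1KO.

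Compared with control cells in hypoxia, HIF1KO cells differed in 5080 genes, 2549 higher and 2531 lower, of which 784 and 822 by at least 2-fold. No other HIF1KO or control line was sequenced, so effects of the knockout and of the line cannot be told apart. WNT5A was at 24.2 against 0.26 CPM, LBH at 64.5 against 2.1 CPM (4.93) and NRP2 at 289 against 13.6 CPM (4.41). ANXA3 (4.30), ABCA1 (4.28), AMOT (4.23), L3MBTL4 (3.98) and FSTL1 (3.80) were higher too. Lower genes were CES1 (0.0834 against 38.2 CPM), SLFN11 (-6.56), NES (1.73 against 150 CPM, -6.43) and CLDN10 (0.225 against 9.86 CPM). EFNB2 (0.369 against 9.72 CPM), EDIL3 (0.49 against 11.8 CPM), AK4 (7.89 against 141 CPM, -4.16) and PLCH2 (-4.08) were lower too. In normoxia WNT5A was at 24.9 against 0.334 CPM and NRP2 was higher by 4.29, while CES1 (0.175 against 57.1 CPM), SLFN11 (0.494 against 38.6 CPM) and ESX1 (0.369 against 12.5 CPM) were lower. The numbers of genes were 4197 in normoxia (1979 higher, 2218 lower; 1155 from these libraries alone, 6348 with the length index) and 6025 in TIFM (3023 higher, 3002 lower; 9053 from these libraries alone).

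Glycolysis genes were lower in hypoxic HIF1KO than in hypoxic control cells, 15 of 20 lower and 1 higher (16 and 1 adjusted over the list alone, median -0.90, adjusted p = 5.03e-09, or 0.0948 with an estimated correlation). They included PGAM1 (383 against 1550 CPM, -2.02 ± 0.12), PFKFB3 (-2.02), PDK1 (-1.65) and PGM1 (-0.92). Of 28 hypoxia-inducible genes 16 were lower and 5 higher (16 and 7 adjusted over the list alone, median -0.53, adjusted p = 3.33e-05, or 0.132 with an estimated correlation). BNIP3 was at -3.40, FAM162A at -2.64 and BNIP3L at -0.98. Epithelial markers were lower in 11 of 17 and higher in 2 (12 and 2 adjusted over the list alone, median -0.70, adjusted p = 1.32e-04). These included the splicing regulator ESRP1 (-3.23), CLDN3 (-2.25), the ductal keratin KRT19 (303 against 1220 CPM, -2.01) and EPCAM (-1.36). Interferon-response genes were lower in 7 of 21 and higher in 3 (7 and 3 adjusted over the list alone, median -0.43, adjusted p = 0.0188), with the antiviral GTPase MX2 at -2.68. Fatty acid synthesis was higher in 9 of 14 with 0 lower (11 and 0 adjusted over the list alone, median 0.47, adjusted p = 2.78e-04), with ACSS2 (1.16), ELOVL6 (2.19) and the regulator SREBF1 (1.01). The amino acid response was higher in 14 of 27 and lower in 3 (14 and 3 adjusted over the list alone, median 0.36, adjusted p = 0.0314, or 0.329 with an estimated correlation). In normoxia, interferon-response genes (9 of 21 lower, 1 higher, 11 and 1 adjusted over the list alone, median -0.61, adjusted p = 0.00633) and epithelial markers (10 of 17 lower, 2 higher, 11 and 2 adjusted over the list alone, median -0.72, adjusted p = 0.00633, or 0.137 with an estimated correlation) were called. In TIFM proliferation was called (19 of 27 lower, 1 higher, 19 and 1 adjusted over the list alone, median -0.73, adjusted p = 2.66e-07).

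Against control in hypoxia, the HIF2KO clones shared large rises and falls of single genes, and interferon-response genes were lower in both. The gap-junction gene GJA1 was at 2020 CPM in A and 392 CPM in B against 9.73 CPM in control (7.70 ± 0.14 and 5.34 ± 0.13), and the EGFR ligands EREG (5.06 and 6.11) and AREG (13.7 and 11.6 against 0.366 CPM) were higher in both. The membrane peptidase MME (37.8 and 12.3 against 0.344 CPM), TMEM92 (6.17 and 4.97), TMEM200C (13.6 and 14.1 against 0.0411 CPM), RBM20 (20.6 and 71.2 against 0.395 CPM) and CD34 (33.7 and 12.9 against 0.449 CPM) completed the rises named by the rule. KRT19 was at 38.5 and 40.9 CPM against 1220 CPM (-4.98 and -4.90), the transcription factor GATA5 at 1.89 and 3.91 against 120 CPM, and IGFBP3 at 0.205 and 0.0904 against 15.8 CPM. Also lower in both were MXRA5 (0.0139 and 0.189 against 35.8 CPM), the interferon-induced OASL (0.25 and 0.177 against 14.3 CPM), C1orf226 (0.271 and 0.383 against 24.5 CPM) and IL15RA (0.109 and 0.558 against 11.7 CPM). EGLN3, a HIF prolyl hydroxylase and itself a HIF target, stood at 10 CPM in control, 15.5 in HIF1KO, 0.0658 in A and 0.473 in B.

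In clone A 5951 genes differed from control in hypoxia (2989 higher, 2962 lower) and in clone B 5113 (2655 higher, 2458 lower). Of these, 1536 were higher and 1448 lower in both clones, where independent lists would share 572 and 525, and 354 went in opposite directions; with the length index 4553 were shared. The covariance of the changes was 0.73 against a simulated 0.04. HIF1KO shared 562 of the higher and 520 of the lower genes with both clones (282 and 264 for independent lists), and 291 and 237 went the opposite way in HIF1KO. Across all genes the covariances of HIF1KO with A and B were 0.25 and 0.15, against 0.04 in simulated unchanged groups that share controls, and the correlations 0.23 and 0.16 against 0.49 and 0.50. Simulated groups sharing the same 3 control libraries had 0 shared calls, which argues against control sampling alone. Traits of the only control line would enter every overlap. Interferon-response genes were lower in 12 of 21 in each clone, with 2 higher in A (12 and 2 adjusted over the list alone, median -0.87, adjusted p = 0.00146) and 3 higher in B (14 and 4 adjusted over the list alone, median -0.93, adjusted p = 6e-04). Examples were MX2 (-2.14) and RIGI (-1.29) in A and IFIH1 (-2.90) and DDX60 (-1.67) in B. Mesenchymal markers were lower in 7 of 14 with 1 higher in A (7 and 1 adjusted over the list alone, median -0.87, adjusted p = 0.00144) and in 6 with 2 higher in B (6 and 2 adjusted over the list alone, median -0.62, adjusted p = 0.00507). MMP2 was at -5.37 in A and -1.88 in B, SPARC at 0.0921 and 0.498 CPM against 5.6 CPM and N-cadherin (CDH2) at -4.51 in B. COL1A1, the main fibrillar collagen gene, was higher in both clones, at 5870 CPM in A and 2290 CPM in B against 94.1 CPM (5.96 and 4.60), whereas COL5A1 was lower in A (-4.52) and higher in B (1.11).

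Cholesterol synthesis genes were lower in the HIF2KO clones in hypoxia, and iron-handling genes in clone A. Cholesterol synthesis had 12 of 22 lower and 0 higher in A (12 and 0 adjusted over the list alone, median -0.42, adjusted p = 0.00801) and 10 lower and 0 higher in B (11 and 0 adjusted over the list alone, median -0.39, adjusted p = 0.0204, or 0.0786 with an estimated correlation). DHCR7 was at -0.60 and -0.70. Iron handling had 8 of 13 lower and 1 higher in A (9 and 1 adjusted over the list alone, median -0.54, adjusted p = 0.00146), led by the haem-degrading HMOX1 (-1.95; -1.78 in B) and including the ferritin gene FTH1 (-1.20). The amino acid response in A was higher in 17 of 27 with 0 lower (17 and 0 adjusted over the list alone, median 0.55, adjusted p = 0.00146, or 0.155 with an estimated correlation; CHAC1, 1.21). In B, 4 more calls were lost with an estimated correlation. The first was that of NRF2 targets (7 of 14 lower, 0 higher, 8 and 0 adjusted over the list alone, median -0.44, adjusted p = 0.00507, or 0.181 with an estimated correlation). Next were epithelial markers (9 of 17 lower, 3 higher, 10 and 3 adjusted over the list alone, median -0.51, adjusted p = 0.0171, or 0.181 with an estimated correlation). Oxidative phosphorylation had the third call (9 of 35 lower, 0 higher, 6 and 0 adjusted over the list alone, median -0.43, adjusted p = 0.0315, or 0.757 with an estimated correlation). The TCA cycle had the last (8 of 16 lower, 1 higher, 9 and 1 adjusted over the list alone, median -0.21, adjusted p = 0.0434, or 0.284 with an estimated correlation). Neither glycolysis (medians 0.05 and 0.16, adjusted p = 0.524 and 0.338) nor the HIF-2 target list (medians -0.42 and 0.02, adjusted p = 0.133 and 0.0914) was called. HK2 was higher in both clones (1.85 and 1.26), and LOXL2 was at -2.53 and CXCR4 at 5.72 in A.

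Many differences of the HIF2KO clones from control were present in normoxia too. Clone A differed from control in 5785 genes in normoxia (2717 higher, 3068 lower) and 7874 in TIFM (4004 higher, 3870 lower), and clone B in 5848 (2750 higher, 3098 lower; 3174 from these libraries alone) and 5392 (2733 higher, 2659 lower). Interferon-response genes were lower in normoxia in 13 of 21 in each clone with 2 higher (13 and 2 adjusted over the list alone in A, 14 and 2 in B, medians -0.69 and -1.25, adjusted p = 2.89e-04 and 4.45e-05). Cholesterol synthesis was lower in 13 and 16 of 22 with 0 higher (13 and 17 adjusted over the list alone, medians -0.71 and -0.66, adjusted p = 9.14e-05 and 1.05e-04). Mesenchymal markers were lower in 8 of 14 in each, with 0 higher in A and 2 in B (9 and 0, and 8 and 2, adjusted over the list alone, medians -0.74 and -0.91, adjusted p = 4.8e-05 and 0.00278). Higher in A was the amino acid response, 20 of 27 with 0 lower (21 and 1 adjusted over the list alone, median 0.82, adjusted p = 1.03e-07). Epithelial markers were lower in B, 10 of 17 with 2 higher (10 and 2 adjusted over the list alone, median -0.81, adjusted p = 4.45e-05).

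In TIFM clone B was lower than control for proliferation, 18 of 27 with 0 higher (19 and 0 adjusted over the list alone, median -0.92, adjusted p = 5.96e-07). It was also lower for the interferon response, 12 of 21 with 2 higher (12 and 2 adjusted over the list alone, median -0.73, adjusted p = 0.00139). HIF-2 targets were lower in 6 of 17 with 2 higher (6 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.00285), and mesenchymal markers in 6 of 14 with 1 higher (6 and 1 adjusted over the list alone, median -0.49, adjusted p = 0.00521). For clone A the 7 list calls in TIFM were lost with an estimated correlation. Its TIFM libraries also stood apart in composition, with 9.55% of counts from ribosomal protein genes against 5.95% in control TIFM, a mean length index of 1.51 against 1.94 and scaling factors of 0.783 to 0.917, so RNA quality may enter these changes. Collagen and matrix was among them (17 of 22 lower, 3 higher, 17 and 3 adjusted over the list alone, median -1.46, adjusted p = 9.77e-04, or 0.368 with an estimated correlation). So was oxidative phosphorylation (29 of 35 higher, 0 lower, 29 and 0 over the list alone, median 0.71, adjusted p = 0.00377, or 0.659).

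Set against the mean of the HIF2KO clones in hypoxia, HIF1KO cells differed in 7067 genes (3586 higher, 3481 lower). IGFBP3 was at 71.2 CPM against 0.205 and 0.0904 CPM, EGLN3 at 15.5 against 0.0658 and 0.473 CPM, and LBH at 64.5 against 0.355 and 1.77 CPM. Iron handling was higher in 8 of 13 and lower in 1 (8 and 2 adjusted over the list alone, median 0.46, adjusted p = 0.00307). Glycolysis was lower in 17 of 20 with 0 higher (17 and 0 adjusted over the list alone, median -0.93, adjusted p = 4.39e-07, or 0.121 with an estimated correlation). By contrast, HIF-2 targets were higher in 10 of 17 and lower in 5 (10 and 5 adjusted over the list alone, median 1.06, adjusted p = 0.0326, or 0.105 with an estimated correlation). The clones also differed from each other in hypoxia, in 4938 genes (2410 higher in A, 2528 lower). KLK4 was at 27 CPM in A and 0.0283 CPM in B, GDA at 18.8 and 0.248 CPM, and GFRA2 at 13.8 and 0.301 CPM. Lower in A was the adhesion receptor ADGRL3, at 0.105 and 17.8 CPM.

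Changing regular medium for TIFM under hypoxia altered 6090 genes in control cells, 2916 higher and 3174 lower, of which 694 and 1032 by at least 2-fold. TXNIP, a glucose-sensing arrestin that restrains glucose uptake, rose from 1.64 to 98 CPM (5.91 ± 0.55) and its relative ARRDC4 from 4.13 to 22.7 CPM (2.46). S100P (4.53), DHRS2 (4.46), the neurotrophin receptor NGFR (3.51), the apoptosis gene HRK (3.17), ZNF185 (2.75) and STKLD1 (2.52) rose as well. The fatty acid desaturase FADS2 fell from 720 to 45.8 CPM (-3.97 ± 0.09), the chemokine CCL2 from 70.3 to 5.13 CPM (-3.77), the transferrin receptor TFRC from 1010 to 83 CPM (-3.61) and INSIG1, a sterol sensor, from 277 to 27.7 CPM (-3.32). TM7SF2 (-3.37), CORO6 (-3.18), DHCR7 (-3.07) and RAB17 (-3.02) also fell.

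The broadest loss in TIFM was that of sterol and fatty acid synthesis: 21 of 22 cholesterol synthesis genes fell and 0 rose (21 and 0 adjusted over the list alone, median -2.33, adjusted p = 2.51e-46). FDFT1 was at -2.87 and HMGCS1 at -1.98. Fatty acid synthesis fell in 11 of 14 and rose in 2 (11 and 2 adjusted over the list alone, median -1.30, adjusted p = 6.67e-20), with ACSS2 at -2.62 and FASN, the fatty acid synthase, at -2.44 (1860 to 343 CPM). Glycolysis genes fell in 15 of 20 and rose in 2 (15 and 2 adjusted over the list alone, median -0.80, adjusted p = 1.46e-07, or 0.108 with an estimated correlation). Those lower included the lactate exporter SLC16A3 (1720 to 430 CPM, -2.00), PGK1 (2690 to 811 CPM, -1.73), PFKFB4 (-2.23) and HK1 (-1.34). In TIFM the amino acid response rose in 18 of 27 and fell in 2 (18 and 2 adjusted over the list alone, median 0.72, adjusted p = 1.07e-09). It included asparagine synthetase ASNS (1.49), the cystine transporter SLC7A11 (50.3 to 241 CPM, 2.26), CTH (2.01) and SLC1A5 (1.22). HIF-2 targets rose in 9 of 17 and fell in 2 (9 and 2 adjusted over the list alone, median 0.59, adjusted p = 0.00103), with TGFA (1.41) and IGFBP3 (53.6 CPM, 1.76). NF-kB and inflammation genes fell in 9 of 16 and rose in 2 (9 and 3 adjusted over the list alone, median -0.66, adjusted p = 0.00103; CXCL1, -2.60). Epithelial markers fell in 10 of 17 and rose in 1 (10 and 2 adjusted over the list alone, median -0.72, adjusted p = 0.0168, or 0.139 with an estimated correlation; KRT8, -2.28). HMOX1 rose by 2.03 to 1090 CPM.

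Hypoxia-inducible genes as a list were not called between the media in control cells: 9 of 28 were higher in TIFM and 10 lower (9 and 13 adjusted over the list alone, median -0.24, adjusted p = 0.32), with STC2 at 1.47 and INSIG2 at -1.23. An added comparison of control cells in hypoxia with TIFM against normoxia with regular medium, chosen after the data were seen, had 26 of 28 of them higher and 0 lower (26 and 0 adjusted over the list alone, median 1.82, adjusted p = 9.64e-33). In the same comparison glycolysis had 8 of 20 higher and 3 lower (8 and 4 adjusted over the list alone, median 0.15, adjusted p = 0.00885, or 0.486 with an estimated correlation), and PGK1 was at 0.05 ± 0.13 (adjusted p = 0.777). There HIF-2 targets were higher in 13 of 17 with 0 lower (14 and 0 adjusted over the list alone, median 1.83, adjusted p = 2.42e-14). Cholesterol synthesis was lower in 20 of 22 with 0 higher (20 and 0 adjusted over the list alone, median -1.55, adjusted p = 2.27e-25), so that TIFM in hypoxia lay below normoxia, whereas hypoxia in regular medium lay above it. This comparison changed 7229 genes (3534 higher, 3695 lower).

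**Figure D3:**
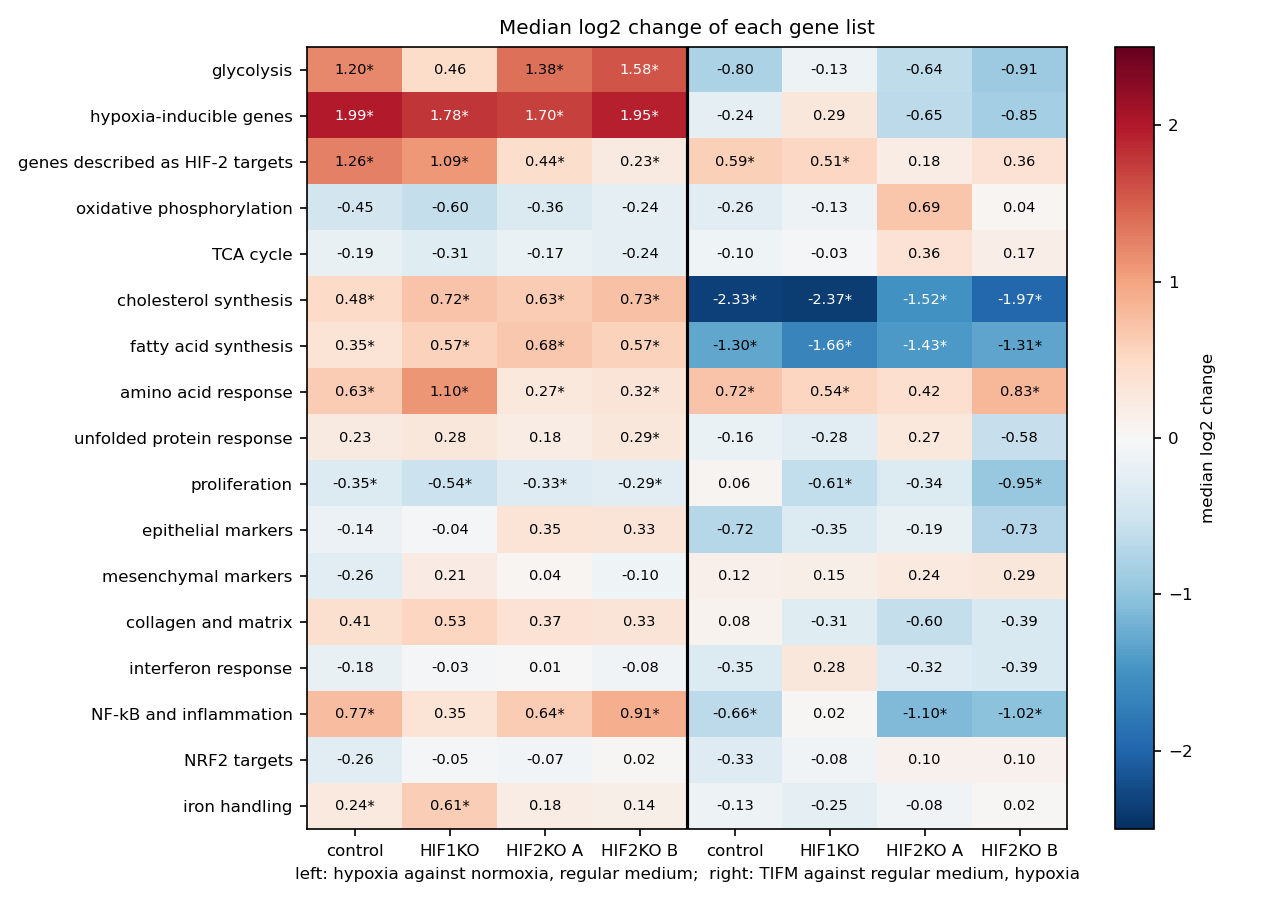
Median log2 change (colour and printed value) of the 17 gene lists with at least 10 tested genes, for hypoxia against normoxia (4 columns on the left) and TIFM against regular medium in hypoxia (4 columns on the right) in each line. An asterisk marks an adjusted p under 0.05 in camera with an estimated correlation, and the TIFM columns of the knockout lines were added after the data were seen. Glycolysis stood at 1.20, 0.46, 1.38 and 1.58 in hypoxia in control, HIF1KO, A and B, and cholesterol synthesis at -2.33, -2.37, -1.52 and -1.97 in TIFM.

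The knockout lines shared the loss of sterol genes in TIFM, and each differed from control in other lists. Added comparisons of TIFM with regular medium changed 4732 genes in HIF1KO (2285 higher, 2447 lower), 7446 in A (3645 higher, 3801 lower) and 6732 in B (3204 higher, 3528 lower), and from the 6 libraries of each line alone 8425 in HIF1KO (7113 with the length index) and 4751 in A. Cholesterol synthesis fell in 21, 18 and 21 of 22 genes, with 0, 1 and 0 higher (the same numbers adjusted over the list alone, medians -2.37, -1.52 and -1.97, adjusted p = 5.37e-71, 5.61e-17 and 7.5e-28). In HIF1KO the fall of glycolysis in TIFM was smaller than in control: the difference was positive for 11 of 20 genes and negative for 0 (16 and 0 adjusted over the list alone, median 0.78, adjusted p = 2.47e-12). The neuronal enolase ENO2 showed this by falling from 171 to 86.9 CPM in control and rising from 59.4 to 104 CPM in HIF1KO (1.79 ± 0.23). For PGK1 the difference was 0.94 and for SLC16A3 0.92. Hypoxia-inducible genes followed, with 10 of 28 positive and 0 negative (14 and 0 adjusted over the list alone, median 0.49, adjusted p = 1.02e-09). BNIP3 fell from 596 to 242 CPM in control and rose from 56.5 to 78.9 CPM in HIF1KO (1.78 ± 0.22, adjusted p = 3.89e-06).

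Some interferon and NF-kB genes fell in TIFM in control cells and rose in HIF1KO. The difference was positive for 5 of 21 interferon-response genes and negative for 0 (8 and 1 adjusted over the list alone, median 0.63, adjusted p = 4.07e-07). There IFIH1 fell by 0.52 in control and rose by 0.80 in HIF1KO (1.32), with DDX60 (1.70) and OASL (1.54). It was positive for 5 of 16 NF-kB and inflammation genes and negative for 0 (6 and 1 adjusted over the list alone, median 0.61, adjusted p = 2.31e-05). NFKB2 fell from 111 to 76 CPM in control and rose from 74.8 to 129 CPM in HIF1KO (1.34), and for ICAM1 the difference was 0.99. Proliferation genes were more negative in HIF1KO, 13 of 27 with 0 positive (16 and 0 adjusted over the list alone, median -0.65, adjusted p = 1.02e-13), such as CDC6 (-1.16), E2F1 (-1.09), RRM2 (-0.82), E2F2 (-1.52) and CCNE2 (-1.52). Fatty acid synthesis was negative for 4 of 14 and positive for 1 (7 and 1 adjusted over the list alone, median -0.34, adjusted p = 2.86e-04; FASN, -1.10). Also negative was the amino acid response, for 5 of 27, with 1 positive (7 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.0129, or 0.248 with an estimated correlation). In all 1257 genes differed (658 positive, 599 negative), and the libraries of these groups alone gave 4487, the length index 3094 and the fit without control normoxia 3 and HIF1KO normoxia 2 gave 2321.

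Proliferation genes fell in TIFM in HIF2KO_B and were not called in control cells (4 of 27 higher, 4 lower, 4 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.673). The difference was negative for 17 of 27 genes and positive for 0 (20 and 0 adjusted over the list alone, median -1.02, adjusted p = 2.11e-21). The mitotic kinases AURKA (131 to 110 CPM in control, 173 to 52.3 CPM in B, -1.48 ± 0.15) and PLK1 (-1.78), with TTK (-1.17) and CDK1 (-1.16), led this list. In HIF2KO_A the proliferation list was negative for 9 of 27 and positive for 2 (15 and 3 adjusted over the list alone, median -0.55, adjusted p = 0.00576, or 0.144 with an estimated correlation), with PLK1 at -1.41. Cholesterol synthesis fell less in A than in control, with 15 of 22 positive and 1 negative (15 and 1 adjusted over the list alone, median 0.87, adjusted p = 2.46e-07; DHCR7, 1.25). In B it had 2 positive and 1 negative (4 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.00998, or 0.0618 with an estimated correlation). The amino acid response rose less in A, 13 of 27 negative and 1 positive (16 and 1 adjusted over the list alone, median -0.53, adjusted p = 9.26e-07), with SLC7A11 at -1.84 and SLC1A4 at -1.40. TXNIP responded less than in control in B (-3.02 ± 0.67, 11.8 to 87.7 CPM). In HIF2KO_A TIFM its libraries held 59.4, 53.6 and 2.28 CPM against 19.3 CPM in regular medium, so its mean there depends on HIF2KO_A TIFM 3, which was also apart in ENO2 (373 against 182 and 165 CPM).

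Further lists in the TIFM response of the clones were called by the preset test only. In A, with the same libraries, hypoxia-inducible genes were among them (9 of 28 negative, 3 positive, 10 and 4 adjusted over the list alone, median -0.48, adjusted p = 7.38e-04, or 0.289 with an estimated correlation; STC2, -1.62). Another was oxidative phosphorylation (26 of 35 positive, 0 negative, 34 and 0 over the list alone, median 1.06, adjusted p = 6.35e-11, or 0.321). Then came the TCA cycle (8 of 16 positive, 0 negative, 10 and 0 over the list alone, median 0.46, adjusted p = 7.38e-04, or 0.144). Collagen and matrix followed (10 of 22 negative, 0 positive, 11 and 0 over the list alone, median -0.91, adjusted p = 1.53e-04, or 0.289). In B one was that of hypoxia-inducible genes (9 of 28 negative, 0 positive, 14 and 2 adjusted over the list alone, median -0.59, adjusted p = 3.72e-08, or 0.0618 with an estimated correlation; NDRG1, -1.60). Collagen and matrix was again one (6 of 22 negative, 0 positive, 7 and 0 adjusted over the list alone, median -0.61, adjusted p = 2.3e-04, or 0.269 with an estimated correlation; COL3A1, -2.45). Further calls of this kind were the unfolded protein response and immune markers in A and oxidative phosphorylation, the unfolded protein response and NRF2 targets in B. Named positive differences in A were ISM2 (2.58), the kinase PIM1 (111 to 592 CPM with an SD of 518 CPM in TIFM) and the metallothionein MT1X (2.10, one of a family of similar genes and thus uncertain). Negative ones were TFAP2C (-2.84), LRATD2 (-2.77), FLG (-2.75), ARRDC4 (-2.61) and CEMIP2 (-2.57). In B they were TM7SF2 (1.96), RAB27B (1.79) and the lipid transporter SPNS2 (108 to 635 CPM, 1.76), and negative HR (-2.54) and the coagulation initiator F3 (-2.41). In A 3314 genes differed from control (1741 positive, 1573 negative; 5266 without control normoxia 3 and HIF1KO normoxia 2). In B 1256 did (461 and 795; 2147 without these libraries, 3215 with the length index, 2887 from the libraries of these groups alone).

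The libraries differed in composition within some groups. Ribosomal protein genes took 11.4% of counts in control normoxia 3 and 10.6% in HIF1KO normoxia 2, against 4.82 to 10.8% in the other 34 libraries, and the length index of these libraries was 0.99 and 1.19. Long minus short genes lay at -0.75 and -0.64 (log2) against the other libraries of their groups. HIF2KO_A TIFM 1 (10.8%, 1.07 and -0.47) was apart too. The fit without the other 2 kept it, so that fit does not test HIF2KO_A in TIFM for this. Most markers of other cell types stayed low: each endothelial marker of the list was under 1 CPM, and of the acinar and endocrine markers only SYP was above 1 CPM, at 13.7 to 28.4 CPM. CD68, a lysosomal gene also found outside macrophages, stood at 390 CPM in HIF2KO_A TIFM, against 129 CPM in control TIFM and 82.3 to 153 CPM over all other groups. KRT19, a ductal keratin, ran from 2260 CPM in control normoxia to 35.6 CPM in HIF2KO_B normoxia.

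**Figure D4:**
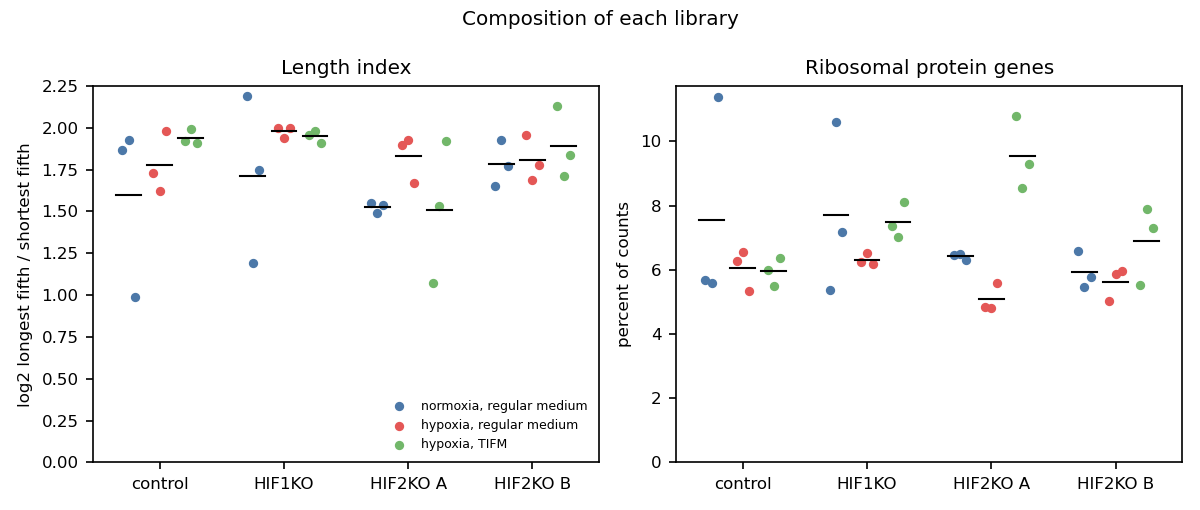
Length index (median log2 CPM of long genes minus that of short genes, left) and percent of counts from ribosomal protein genes (right) in each of the 36 libraries, by line and condition, with a bar at each group mean. Control normoxia 3 (0.99, 11.4%) and HIF1KO normoxia 2 (1.19, 10.6%) lie apart from the other libraries of their groups, as does HIF2KO_A TIFM 1 (1.07, 10.8%).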

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

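The test for TIFM cultures without hypoxia, the test for loss of long transcripts and the test for depth were chosen only after the results they concern had been seen. The results in this part stand here because the change in a knockout line differed from that in control cells by a test of the difference itself, for a count of genes, for a gene list, or for a named gene that changed in both lines with opposite signs.

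The response to hypoxia differed from that of control in 199 genes in HIF1KO, 132 in HIF2KO_A and 118 in HIF2KO_B, and the response to TIFM in 1257, 3314 and 1256. Median differences of lists called in the response of HIF1KO to hypoxia were -0.61 for glycolysis, -0.24 for hypoxia-inducible genes, 0.25 for cholesterol synthesis, 0.29 for fatty acid synthesis, 0.44 for the amino acid response and -0.21 for proliferation. In HIF2KO_A they were -0.19 for hypoxia-inducible genes, -0.46 for HIF-2 targets, 0.22 for cholesterol synthesis, 0.33 for fatty acid synthesis and -0.30 for the amino acid response. In HIF2KO_B they were 0.38 for glycolysis, -0.55 for HIF-2 targets, 0.25 for cholesterol synthesis, 0.09 for fatty acid synthesis, 0.15 for the unfolded protein response, 0.44 for epithelial markers and -0.05 for iron handling. In the response to TIFM they were, in HIF1KO, 0.78 for glycolysis, 0.49 for hypoxia-inducible genes, -0.34 for fatty acid synthesis, -0.20 for the amino acid response, -0.65 for proliferation, 0.63 for the interferon response and 0.61 for NF-kB and inflammation. In HIF2KO_A they were -0.48 for hypoxia-inducible genes, 1.06 for oxidative phosphorylation, 0.46 for the TCA cycle, 0.87 for cholesterol synthesis, -0.53 for the amino acid response, 0.33 for the unfolded protein response, -0.55 for proliferation, -0.91 for collagen and matrix and 0.95 for immune markers. In HIF2KO_B they were -0.59 for hypoxia-inducible genes, 0.36 for oxidative phosphorylation, 0.26 for cholesterol synthesis, -0.39 for the unfolded protein response, -1.02 for proliferation, -0.61 for collagen and matrix and 0.30 for NRF2 targets.

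With an estimated correlation these calls held for all 6 lists of the response of HIF1KO to hypoxia, for all in HIF2KO_A but hypoxia-inducible genes, and in HIF2KO_B for HIF-2 targets, cholesterol synthesis and epithelial markers. In the response to TIFM they held for all in HIF1KO but the amino acid response, in HIF2KO_A for cholesterol synthesis and the amino acid response, and in HIF2KO_B for proliferation. The other lists named lost their call.

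Genes that changed with opposite signs in the response to hypoxia, with the difference of the log2 changes, were DOK3 (-1.65) and PGAM1 (-1.15) in HIF1KO and EREG (1.38) and SLC4A11 (1.17) in HIF2KO_A. In the response of HIF1KO to TIFM they were OAS2 (3.60), CCL5 (2.28), C15orf48 (1.90), ANO9 (1.89), APOL1 (1.86), ENO2 (1.79), BNIP3 (1.78), DDX60 (1.70), NFKB2 (1.34), BIRC3 (1.33), IFIH1 (1.32), ICAM1 (0.99), TNFAIP2 (0.93), SESN2 (0.76), ELOVL5 (-0.96), ATF3 (-1.03) and OLFM2 (-1.72). In HIF2KO_A they were ISM2 (2.58), FRMD3 (2.48), SDF2L1 (1.82), NDUFB5 (1.06), SDHB (0.96), CALR (0.82), CYC1 (0.75), ATF3 (-0.96), CBS (-1.09), LOXL2 (-1.38), TMEM200C (-2.51) and LRATD2 (-2.77). In HIF2KO_B they were CCDC183 (1.72), KCNK15 (1.70), LOXL2 (-0.91), BHLHE40 (-1.14), CDK1 (-1.16), TTK (-1.17), COL5A1 (-1.28), ARG2 (-1.91) and HR (-2.54). The values of OAS2, FRMD3 and TMEM200C involve group means under 0.5 CPM and are unreliable.

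Glycolysis genes were lower in TIFM than in regular medium in hypoxic control cells by the preset test (adjusted p = 1.46e-07), a call lost with an estimated correlation (adjusted p = 0.108). With the length index as a covariate the median was -0.69, and with RLE factors it lay -0.79 from that of all genes, so neither a loss of long transcripts nor the scaling factors accounted for it by the criteria set. Whether cultures had missed hypoxia cannot be told. Hypoxia-inducible genes in TIFM lay 1.82 above normoxia (median), but no TIFM normoxia group separates medium from oxygen. A difference in glucose or lactate between the media remains possible, and the composition of TIFM is not given here.

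Control normoxia 3 and HIF1KO normoxia 2 lay apart from the other libraries of their groups. Long genes lay lower than short ones, relative to the other libraries of the group, by a log2 value of -0.64 in the library nearer to 0, in line with a loss of long transcripts in these libraries. Low depth was set aside for HIF1KO normoxia 2, which held 23.2 M counts, the highest of its group, and for control normoxia 3, at 19.7 M the lowest of its group, because the 3 libraries with smaller totals lay at -0.29 or above on the same measure; these criteria were set after the totals were seen and replaced earlier ones. Both libraries correlated best with their own line, by a margin of at least 0.64, which speaks against a library of another line under these labels. No biological group in the design separates these libraries from the others.

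The HIF2KO clones differed from each other in hypoxia. Across the called genes the difference in normoxia correlated with that in hypoxia at r = 0.93, in line with differences present before hypoxia. Windows of 25 neighbouring genes with a median beyond 0.3 made up 21.2%, against at most 2.58% after shuffling, which is consistent with copy number differences; comparisons within control cells also exceeded their shuffles (3.69 against 1.11% for hypoxia), only 26.1% of 4845 called genes lay in such windows with the same sign, and no DNA was measured here. With the length index as a covariate 100% of the called genes were called, so loss of long transcripts did not account for the difference. Off-target edits, clonal selection and unequal loss of HIF-2α cannot be told apart with these data.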

How the results depend on the processing

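The fit without control normoxia 3 and HIF1KO normoxia 2 and the fit with a length index were chosen only after the result had been seen. With 3 libraries per group, small changes are missed, above all in differences of responses, and counts near 0 give no usable change. No result reversed its direction under the alternatives run for it. Lists were not run with DESeq2, without the filter, from only the groups compared or with single libraries left out, and named genes not without the filter or from only the groups compared. Of 147 list calls 84 held with an estimated correlation, and the other lists lost their call. Replicate numbers did not pair the libraries: 198 pairs with the same number had a median r of -0.00, 69 of them were over 0.1, and 11 of 36 libraries correlated best with their own number. With the replicate number as a block 2818 genes changed in control hypoxia against 3025. Of 817 named gene results and 147 lists, 5 and 1 then lost their call. Without the 2 libraries with few long transcripts 13 and 7 did, with the length index 2 and 2, with RLE factors 1 and 1, and with single libraries left out 286 of 7380 named gene results. All these lists were among those lost with an estimated correlation.

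Counts below moved by more than 1.5 times, and the cause was not tested. A fit of only the groups compared gave 438 genes for hypoxia in control, 3264 in HIF1KO, 6941 in HIF2KO_A and 4743 in HIF2KO_B. It gave 1155 for HIF1KO and 3174 for HIF2KO_B against control in normoxia, and 9053 for HIF1KO against control in TIFM. For differences in the response to hypoxia it gave 43 (HIF1KO) and 67 (HIF2KO_B), and in the response to TIFM 4487 and 2887. DESeq2 gave 379, 237 and 223 for the response to hypoxia in HIF1KO, A and B, 99 genes shared by the clones, and 120, 181 and 140 control hypoxia genes nearer to 0. Without the 2 libraries with few long transcripts, hypoxia gave 4656 in A and 3342 in B, the response to hypoxia in A 472, the response to TIFM 2321, 5266 and 2147, the clones shared 100 genes of the response to hypoxia, and 279 control hypoxia genes lay nearer to 0 in A. With the length index, hypoxia gave 4592 in control and 4596 in B, and HIF1KO in normoxia 6348. The response to hypoxia then gave 836, 543 and 434, the response to TIFM 3094 in HIF1KO and 3215 in B, and 4553 genes were shared by the clones in hypoxia, 193 in the response to hypoxia and 1826 by all knockout lines. Of control hypoxia genes, 2277 of 4592 were then called in A and 2851 in B, and 244, 416 and 254 lay nearer to 0. For TIFM in the knockout lines, added later, the groups alone gave 8425 in HIF1KO and 4751 in A, and the length index 7113 in HIF1KO.

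Leaving out each library in turn gave ranges of 1892 to 3536 for hypoxia in control, 3614 to 6478 in HIF1KO, 1463 to 1670 in HIF2KO_A and 1518 to 1622 in HIF2KO_B. TIFM in control gave 5237 to 5481. Against control, HIF1KO, A and B gave 4193 to 4695, 5206 to 5402 and 4199 to 4595 in hypoxia, 3546 to 4715, 5045 to 6053 and 4652 to 5966 in normoxia, and 5162 to 5237, 7071 to 8326 and 4602 to 4728 in TIFM. The response to hypoxia gave 126 to 398, 94 to 186 and 78 to 121, and the response to TIFM 853 to 1059, 2229 to 4741 and 930 to 1092. HIF1KO against the HIF2KO mean gave 6167 to 6846 and clone A against B 4195 to 4275. Genes shared by the clones numbered 2512 to 2805 in hypoxia and 44 to 61 in the response to hypoxia, and those shared by all knockout lines 859 to 1036. Control hypoxia genes called in HIF1KO, A and B numbered 1472 to 2805, 985 to 1592 and 994 to 1236, and those nearer to 0 numbered 39 to 99, 81 to 142 and 55 to 82.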

Other observations

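The choice of chromosome medians to print was made only after the result had been seen; the splits were set earlier. Interferon-response genes were lower in the knockout lines than in control already in normoxia, with medians of -0.61, -0.69 and -1.25 in HIF1KO, HIF2KO_A and HIF2KO_B. NOTCH3 rose more with hypoxia in HIF1KO than in control (2.51), and the EGFR ligand EREG stood at 47.5 and 98.1 CPM in hypoxic HIF2KO_A and HIF2KO_B against 1.41 CPM in control. Median log2 differences of whole chromosomes between clones A and B in hypoxia reached 0.40 for chromosome 7, -0.37 for chromosome 9 and -0.38 for chromosome 15. Against control in normoxia, HIF1KO lay at 0.36 on chromosome 9, -0.39 on chromosome 10 and -0.42 on chromosome 13, and clone A at -0.52 on chromosome 11.

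Other splits of the same libraries were tested for chance. Comparisons of 3 against 3 libraries had 10 splits, too few to exclude chance. In each, 1 of 10, the real one, was highest (highest other 0). The real counts were 438, 3264, 6941 and 4743 for hypoxia in control, HIF1KO, A and B, 8048 for TIFM in control, 7382, 7361 and 6742 for the knockout lines against control in hypoxia, 1155, 3983 and 3174 in normoxia, 9053, 5475 and 7062 in TIFM, and 6909 for clone A against B. For the added comparisons they were 5090 for control cells in hypoxia with TIFM against normoxia and 8425, 4751 and 7757 for TIFM in HIF1KO, A and B.

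For HIF1KO against the HIF2KO mean 1 of 84 splits reached 6204 genes (highest other 4062). In the response to TIFM, 1 of 100 draws each reached 4487 in HIF1KO and 2887 in HIF2KO_B (highest others 4153 and 2542). The draws mix lines that differ in many genes, so they cannot decide on chance. For HIF2KO_A 3 of 100 reached 2922, with 7611 as the highest other. In the response to hypoxia, 4 of 100 draws reached 43 in HIF1KO (highest other 3665), 3 of 100 reached 91 in HIF2KO_A (highest other 1664) and 2 of 100 reached 67 in HIF2KO_B (highest other 7202). Some draws gave many times the real count. For HIF2KO_B in hypoxia and HIF2KO_A in TIFM they included the swap of the lines in 1 condition. Fixed differences between the lines may play a part in the others, which was not tested.

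HIF1KO cells are hypothesised to keep part of the hypoxia response through HIF-2α, with glycolysis and BNIP3 resting more on HIF-1α. The lower response of glycolysis in HIF1KO (median -0.61) and of HIF-2 targets in the clones (-0.46 and -0.55) would be consistent with this, but the response to hypoxia gave only 43 genes in a fit of the HIF1KO and control libraries alone. A line with HIF-2α restored, or a double knockout, would test it.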
